A study of Homo sapiens with 12 samples.

How the data were processed

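MicroRNA levels were measured in RKO cells, a human colon carcinoma line, on one-colour Agilent miRNA arrays. The labels give 2 isogenic forms of the line, with wild-type p53 and without p53 (p53-null), each transfected with a negative-control siRNA or with an siRNA against casein kinase 1 alpha (siCK1a) at 100 nM and collected after 48 h. Each of the 4 groups had 3 arrays, 12 in all, called biological replicates 1, 2 and 3 in the labels. Replicates 1 and 2 of every group were on one slide and replicate 3 on another, so that both slides held all 4 groups. Each group had the same place in the order of arrays on the slide throughout, so position and group cannot be told apart. The labels do not say how far apart the cultures were kept, and p-values therefore measure the spread between these samples, which may be technical. The CSNK1A1 transcript is not measured by a miRNA array, so the silencing was taken from the labels and not checked here, as were the genotypes.

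The deposited array tables give, per the file headers, the mean intensity of the spots of each probe on a linear scale, the standard deviation over those spots as an intensity, and, as other deposited quantities, the number of spots kept and the number left out as outliers. The submitters' processing notes name Agilent Feature Extraction, with no version. No background subtraction or scaling between arrays could be seen in these values. The authors also deposited a table of processed values, quantile normalized intensity on a linear scale, in which the column medians of 4782 probes lay between 31.28 and 31.29. The ranks within each of its columns matched those of the corresponding array column, which settled the array and the direction of each column, and it was used as an alternative, with its values taken as linear. Any further step by the authors is not given in the sources used here. Per-array columns of bad spots and of p-values, 24 in all, were not used, nor was a second copy of the authors' values with positive controls.

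The array tables held 4818 probes, of which 44 were control probes. The remaining 4774 probes named 2006 miRNAs, with 1 probe for 6 miRNAs, 2 for 1547, 3 for 138 and 4 for 315; 21 of these probes lacked a value on some array and were left out. Names are those of the array design. The design fixed beforehand assumed processed scanner signals with flags for each spot. The files held probe means with no such flags, so the background was corrected with normexp and an offset of 50 on each array over all probes, in limma 3.58.1 under R 4.3.3. Probe signals were then summed per miRNA. A miRNA counted as detected on an array where the mean of any of its probes exceeded a negative-control limit. This limit estimated the 95th percentile of single spots of the 7 negative-control probes. It was taken from their pooled mean and standard deviation under a normal distribution. Detection reached 23.1% of the miRNAs on average, so each array was divided by its 75th percentile over the 382 miRNAs detected on all arrays. Values below a floor of 128.85 (log2 7.01) were set to the floor, and log2 was taken. The offset adds a constant to every probe and thereby makes fold changes smaller than those of the hybridized RNA. A miRNA detected on no array of a group has only a bound there, written as at least a given fold: the bright group's mean over the dim group's, with the higher of the lowest detected signal and its own signal taken on each dim array. In each of the 5 comparisons 0 called miRNAs had a probe that changed by over 0.2 log2 in the opposite direction.

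The spots kept per array numbered 58911 to 59569 and the outlier spots 2769 to 3427. The mean negative-control signal was 22.2 to 51.7, highest on the siCK1a array of replicate 3 in wild-type cells, and 416 to 491 miRNAs were detected per array. The 75th percentile of detected miRNAs was 5.15 to 7.79 times the negative-control signal. Replicates of a group were compared before averaging: 27.3% to 79.0% of probes differed by more than 2 standard errors of their spots, and no array repeated another. The number of arrays limits the precision. The median standard error of a log2 change was 0.0923, and 0.131 for a difference between changes.

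The 469 miRNAs detected on all 3 arrays of at least 1 group were tested with limma (lmFit and eBayes) in one fit of the 4 group means over all 12 arrays, with 8 residual degrees of freedom. The 5 comparisons were siCK1a against control siRNA in wild-type and in p53-null cells, the difference between these changes, and p53-null against wild-type cells under each siRNA. A miRNA was called at an adjusted p (Benjamini-Hochberg, within a comparison) under 0.05. Intervals are 95% confidence intervals. The 17 lists of miRNAs were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, which held for 15. The lists were the p53-induced miRNAs, the miR-17-92 and paralogue clusters, Wnt/MYC-linked miRNAs, the let-7/miR-98, miR-200/205, miR-15/16/424/503, miR-29 and miR-30 families, the miR-23/27/24 clusters, miR-181/221/222, inflammation-linked miRNAs, the 14q32 and C19MC clusters, markers of blood cells, of stroma and endothelium, and of muscle, liver and nerve, and GC-rich or structural-RNA-like annotations, whose signals can follow RNA quality. The C19MC cluster and the blood cell markers each had 1 tested member and no test. Camera was repeated with an estimated correlation, and fry was run as another set test. No call of camera in any comparison held with an estimated correlation.

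Named miRNAs followed a rule: per comparison, the 12 largest rises and 12 largest falls among called miRNAs whose 3 arrays of one group all lay on one side of the other group's 3, the called miRNAs of the difference between changes, the known p53 targets of the miR-34, miR-192/194/215 and miR-143/145 groups and miR-107 in every comparison, and up to 4 members with the smallest p from each described list. A few others were named after their values were seen: miR-210 in wild-type cells, miR-22-3p, miR-221-3p, miR-222-3p, miR-125b-5p, miR-155-5p, miR-3663-3p and miR-4739 in p53-null cells, miR-22-3p, miR-15a-5p and miR-1246 for the difference, and some members of the miR-30, miR-200 and inflammation-linked lists and miR-7-5p for the genotypes. The design, the alternatives, the lists and this rule were fixed before the data were examined, except for 5 alternatives of background, GC content and list members that were chosen after seeing the data. On simulated data for siCK1a in wild-type cells with 458 tested miRNAs, 17 of 49 miRNAs changed by 0.4 log2 were called (34.7%, median estimate 0.19) and 35 of 50 changed by 1 log2 (70.0%, median estimate 0.41), with 4 of 359 unchanged ones called. In the simulated p53-null comparison with no change, 1 of 458 was called. The simulated noise took its size from log2 values after the offset, and the offset then shrank it again. It was also independent between miRNAs. These rates can therefore be better than those of the real data.

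Whether equal replicate numbers pair arrays was checked through the correlation of same-numbered arrays' deviations from their group means. Every pair exceeded 0.1 for siCK1a in p53-null cells (lowest 0.36) and for p53 genotype with control siRNA (lowest 0.103) and with siCK1a (lowest 0.17), where the numbers therefore paired the arrays, as a property of the data and not of a stated day or batch. They did not pair the arrays in wild-type cells, where replicate 3 gave -0.42. Slide was tried as a block and slide 1 was analysed alone. Other alternatives changed the scaling, floor, filter, background, probe summary, variance model, threshold, set test and the arrays included. Their effects are given after the results. miRNA genes were placed by name in the RefSeq annotation of GRCh38.p14, used only to find neighbouring hairpins.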

Results

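One-colour arrays, 12 in all, measured miRNAs in RKO cells, a human colon carcinoma line used here in isogenic forms with wild-type p53 and without p53. Cells of both forms received a control siRNA or an siRNA against casein kinase 1 alpha (CK1a), the kinase that primes beta-catenin for degradation and restrains p53. Each of the 4 groups had 3 biological replicates, replicates 1 and 2 on one slide and replicate 3 on another. Of 2006 miRNAs on the array, 416 to 491 were detected per array, and 469 were tested. Signals are background-corrected, scaled array intensities in arbitrary units with a floor of 128.85, and log2 changes come from the limma fit over all 12 arrays. Of 12 mature miRNAs known as p53 targets, 5 (miR-34b-3p, both arms of miR-34c, miR-143-3p and miR-145-5p) were detected on no array, and 7 were tested.

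The first comparison asked which miRNAs respond to CK1a loss in cells that carry p53. miR-34a-5p, a direct transcriptional target of p53 that represses cell-cycle and survival genes, rose from 737 ± 60.2 to 1428 ± 166 (SD, n = 3 each; log2 change 0.95, SE 0.09, adjusted p = 1.3e-06). miR-34b-5p, made from another p53-responsive locus, rose from 178 ± 17 to 234 ± 9.57 (log2 change 0.40, adjusted p = 0.0055). Its other arm, miR-34b-3p, was detected on no array. A probe of miR-34b-5p resembles those of miR-34a-5p in sequence, and shared signal was not separated from a response of its own. miR-22-3p, a p53-linked repressor of CDKN1A, rose from 847 ± 15.2 to 1179 ± 38.6 (0.48, adjusted p = 4.5e-04). miR-7-5p, which targets EGFR and insulin-pathway transcripts, had the largest fall among called miRNAs, from 1621 ± 53 to 779 ± 82.7 (-1.06, SE 0.07, adjusted p = 8.1e-08). The largest rise was that of miR-1246, a p53-linked annotation whose sequence also lies in U2 small nuclear RNA, from 939.8 ± 121 to 2718 ± 310 (1.53, adjusted p = 3.5e-08).

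In these wild-type cells 17 of the 469 miRNAs passed the test, 12 higher and 5 lower, and 53 had an unadjusted p under 0.05. miR-222-3p, which targets the cell-cycle inhibitor CDKN1B, rose from 593.6 ± 116 to 879.2 ± 52.4 (0.58, adjusted p = 0.0028), and miR-30a-5p rose by 0.43 (adjusted p = 0.0040). The other rises were those of miR-3960 (0.76), miR-6090 (0.68), miR-4530 (0.47), miR-3665 (0.44), miR-3663-3p (0.43) and miR-4739 (0.39). The inflammation-linked miR-155-5p fell by 0.39 (adjusted p = 0.0036), miR-15a-5p, which targets BCL2, fell by 0.35 (adjusted p = 0.027), and miR-374b-5p also fell by 0.35 (adjusted p = 0.027). The hypoxia-induced miR-210 passed as well (-0.64, adjusted p = 0.027), although its arrays overlapped between the groups. It is named because it completes the 5 lower miRNAs, a choice made after its values were seen. Among the other p53 targets, the log2 changes were 0.25 for miR-194-5p (adjusted p = 0.14), 0.17 for miR-192-5p (0.46), 0.14 for miR-34a-3p (0.57), 0.10 for miR-107 (0.79) and 0.07 for miR-215 (0.87), none of which passed.

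Of the lists, 4 of 15 passed in wild-type cells. In the list of p53-induced miRNAs 4 of 17 tested members rose (miR-1246, miR-34a-5p, miR-22-3p and miR-34b-5p) and miR-15a-5p fell, against 5 higher and 2 lower when adjusted over the list alone. Its median log2 change was 0.10 and its camera adjusted p 6.8e-04 (adjusted p = 0.51 with an estimated correlation). In the GC-rich or structural-RNA-like list, whose signals can follow RNA quality, 6 of 32 rose and 0 fell (9 and 0 when adjusted over the list alone; 9 and 1 at an unadjusted p under 0.05). Its median was 0.13 and its adjusted p 4.9e-06 (adjusted p = 0.51 with an estimated correlation). miR-1246, miR-3960, miR-6090 and miR-4530 led it, and miR-1246 counts in both of these lists. miR-1246 rose in p53-null cells too (2.10, against 1.53 in wild-type cells). Its part in the call of the p53-induced list is therefore no evidence of a response through p53. The GC-rich list's median was 0.42 and 0.24 between the arrays of replicates 1 and 2 and -0.32 between those of replicate 3. The medians of all miRNAs in these 3 pairs were 0.14, 0.00 and -0.22. The MYC-driven miR-17-92 and paralogue clusters shifted down (median -0.14, adjusted p = 0.0085, and adjusted p = 0.51 with an estimated correlation). Of their 17 members 16 had a negative change, 3 at an unadjusted p under 0.05, and limma called 0. Examples are miR-18b-5p (-0.24), miR-93-5p (-0.21), miR-18a-5p (-0.20) and miR-106b-5p (-0.17). The miR-15/16 family shifted down too (median -0.15, adjusted p = 0.023, and adjusted p = 0.51 with an estimated correlation). In it miR-15a-5p alone of 8 passed, against 3 lower when adjusted over the list alone. The changes were -0.38 for miR-15b-5p (adjusted p = 0.13), -0.29 for miR-16-5p (0.24) and -0.15 for miR-16-2-3p (0.56).

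The remaining 11 lists did not pass: miR-181/miR-221/miR-222 (adjusted p = 0.062), miR-30 (0.14), miR-29 (0.16), miR-200/miR-205 (0.16), markers of muscle, liver and nerve (0.25), Wnt/MYC-linked (0.58), let-7/miR-98 (0.58), inflammation-linked (0.58), stromal and endothelial markers (0.58), 14q32 (0.66) and miR-23/27/24 (0.90). In let-7/miR-98 and miR-23/27/24 the signs of median, mean and test differed. Fry called 0 lists after adjustment. Calls in wild-type cells depended on single arrays. Without the siCK1a array of replicate 3, which had the highest background, 70 miRNAs passed. There were 26 without the siCK1a array and 11 without the control array of replicate 1, 10 without all of replicate 1 and 3 without replicate 2. On slide 1 alone, that is without replicate 3, 80 were higher and 27 lower, against 18 calls in all with slide as a block. With the authors' values 24 were higher and 28 lower. Without the siCK1a array of replicate 3 the p53-induced list did not pass (adjusted p = 0.147). The miR-17-92 and miR-15/16 lists lost their calls without the siCK1a array of replicate 1 (0.42 and 0.115), and the latter also without the control array of replicate 2 (0.0757). miR-34b-5p lost its call without the control array of replicate 1 (0.35, adjusted p = 0.0535), whereas miR-34a-5p, miR-7-5p, miR-22-3p and miR-1246 passed without each of the 12 arrays in turn. In all, 11 of the 17 called miRNAs did so.

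**Figure D1:**
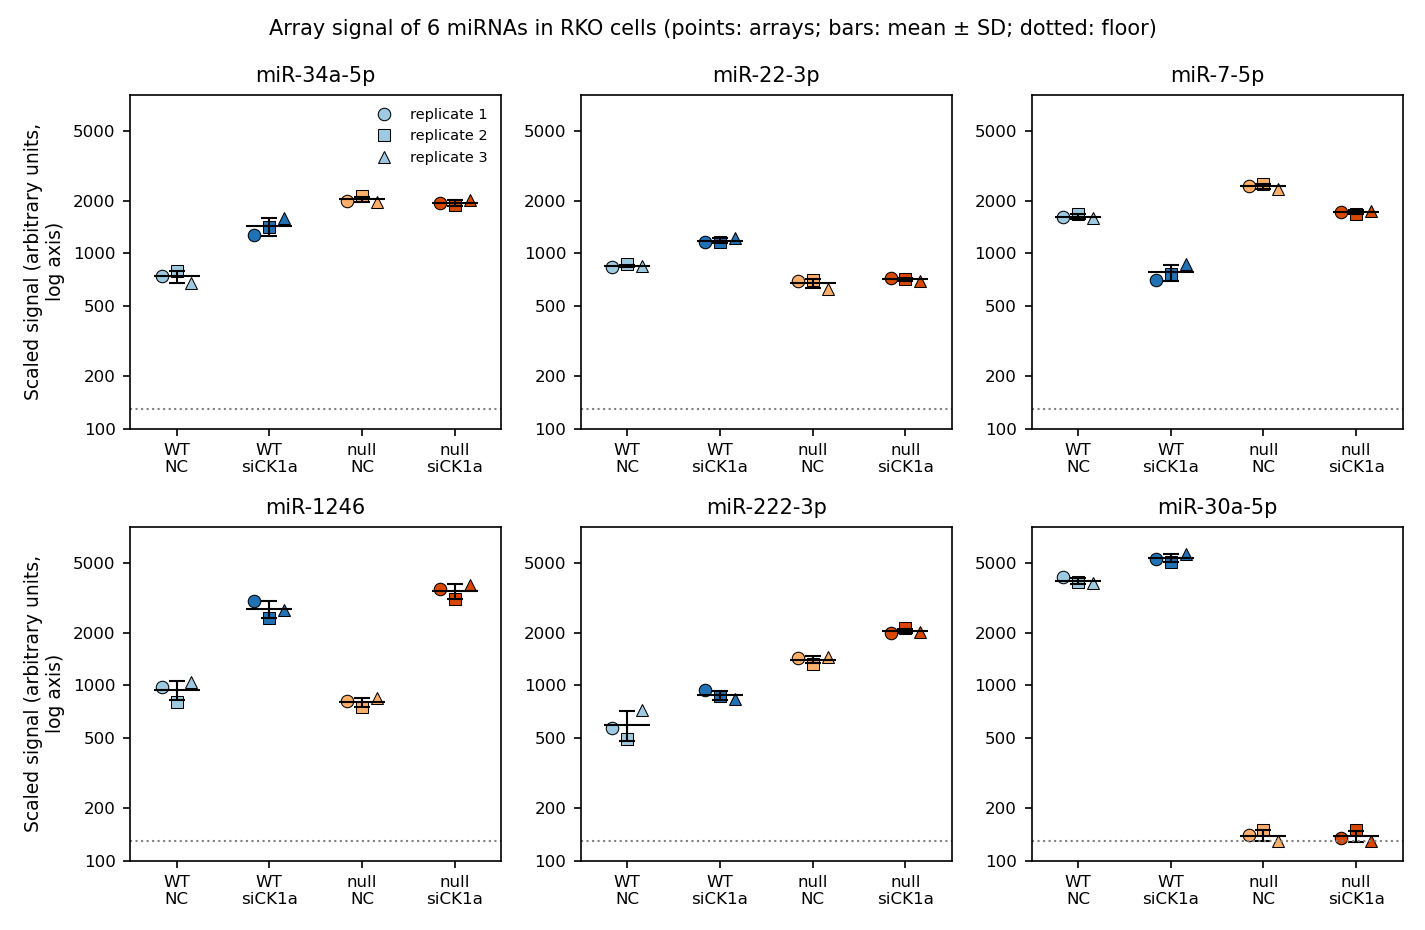
Scaled signal (arbitrary units, log axis) of 6 miRNAs in wild-type (WT) and p53-null RKO cells with control siRNA (NC) or siCK1a; points are arrays, with a symbol for each replicate, bars the mean ± SD (n = 3) and the dotted line the floor of 128.85. miR-34a-5p lay at 737 in WT NC, 1428 in WT siCK1a, 2028 in null NC and 1937 in null siCK1a, and miR-30a-5p lay near the floor in both null groups.

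The same silencing in p53-null cells gave no detectable change of miR-34a-5p, at 2028 ± 79.3 with control siRNA and 1937 ± 65.3 with siCK1a (-0.07, adjusted p = 0.78), nor of miR-34b-5p (0.01, adjusted p = 0.96) or miR-22-3p (0.08, adjusted p = 0.69). miR-7-5p fell by 0.50, from 2418 ± 79.7 to 1714 ± 45.1 (adjusted p = 5.0e-04), and miR-7-1-3p, from the other arm of one of its hairpins, fell by 0.34 (adjusted p = 0.010). miR-1246 rose from 802.5 ± 48.1 to 3448 ± 326 (2.10, adjusted p = 2.3e-10). miR-222-3p rose from 1399 ± 66.1 to 2042 ± 61.4 (0.55, adjusted p = 0.0021), its neighbour miR-221-3p rose by 0.38 (adjusted p = 0.019) and miR-125b-5p by 0.48 (adjusted p = 0.0021), all 3 outside the largest rises and named after their values were seen.

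In the p53-null cells 47 miRNAs passed, 30 higher and 17 lower, with 94 at an unadjusted p under 0.05. The largest rises after miR-1246 were those of miR-6090 (1.15), miR-3960 (1.13), miR-4465 (1.11), miR-4530 (1.02), miR-4281 (0.94), miR-4516 (0.91), miR-6089 (0.80), miR-3665 (0.78), miR-1915-3p (0.76), miR-642a-3p (0.73) and miR-630 (0.68). The largest falls were those of miR-494 (-0.94, adjusted p = 0.020), the hypoxia-induced miR-210 (-0.75, adjusted p = 0.0040), miR-3676-5p (-0.57), miR-21-3p (-0.51, adjusted p = 6.8e-05), whose sister arm miR-21-5p is a well-known oncogenic miRNA, miR-513a-5p (-0.51), miR-196b-5p (-0.43), miR-130b-3p (-0.41), miR-374b-5p (-0.37), miR-1273g-3p (-0.34) and miR-29b-1-5p (-0.29). The p53 targets miR-192-5p (0.18, adjusted p = 0.24) and miR-107 (0.17) did not pass, nor did miR-194-5p, miR-215 or miR-34a-3p.

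The GC-rich list had the smallest camera p here too: 13 of its 32 tested members rose and 0 fell (16 and 1 when adjusted over the list alone; 18 and 1 at an unadjusted p under 0.05). Its median was 0.24, replicate by replicate 0.30, 0.29 and 0.21, and its adjusted p 8.4e-18 (adjusted p = 0.68 with an estimated correlation). The miR-17-92 and paralogue clusters shifted down (median -0.12, adjusted p = 0.025, and adjusted p = 0.89 with an estimated correlation). All 17 members had a negative change, and miR-19b-3p (-0.29, adjusted p = 0.034) and miR-92a-3p (-0.27, adjusted p = 0.040) fell, the same number as when adjusted over the list alone. This list's call ended under several scalings, with adjusted p = 0.55 for the 75th percentile over all miRNAs, and without the siCK1a array of replicate 1 (0.0793) or of replicate 2 (0.136). In the p53-induced list miR-1246 alone of 17 rose (adjusted p = 0.31; 1 when adjusted over the list alone), and the other 12 lists had an adjusted p of 0.30 to 0.87, fry calling 1 list. With the brightest probe of each miRNA 32 were higher and 41 lower. The count of 47 was 44 with a replicate block and 47 with slide as a block. It was 76 on slide 1 alone and 78 without the wild-type siCK1a array of replicate 3. It was 29 without the control array of replicate 1 and 29 without its siCK1a array, 26 and 27 without those of replicate 2, 30 without the control array of replicate 3, and 13 without all of replicate 2. Of 32 named calls in p53-null cells 19 passed without each of the 12 arrays in turn. Among those that did not, miR-494 lost its call without the control array of replicate 1 or 3 or the siCK1a array of replicate 2 or 3 (-1.18 to -0.82 over all 12 omissions).

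**Figure D2:**
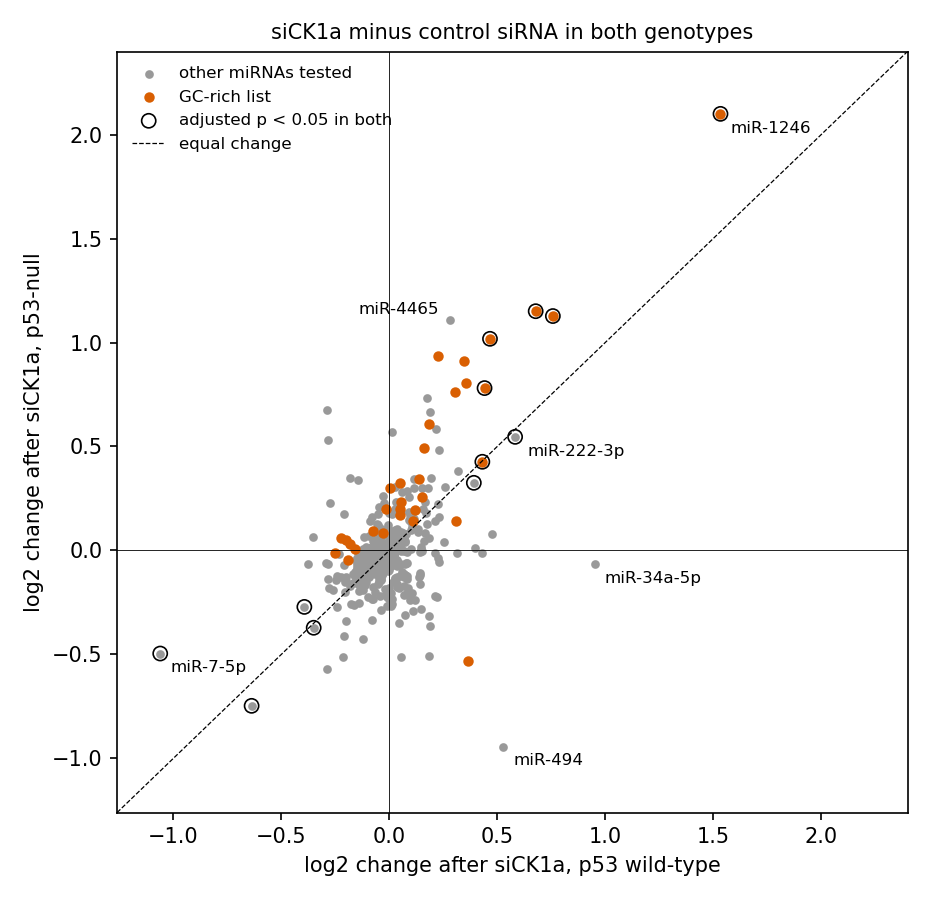
Log2 change after siCK1a against control siRNA in wild-type cells (x axis) and p53-null cells (y axis) for the 469 tested miRNAs, each point a mean over 3 against 3 arrays; members of the GC-rich list are coloured and miRNAs that passed in both are ringed. miR-34a-5p lies at 0.95 and -0.07, miR-1246 at 1.53 and 2.10, and miR-7-5p at -1.06 and -0.50.

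Both cell lines shared 12 calls, 8 higher and 4 lower, where independent lists would share 1.70 (one-sided Fisher's exact test, p = 1.1e-09). Of these, 6 of the 8 rises were members of the GC-rich list. Outside it 2 rises and 4 falls were shared, where independent lists would share 0.856 (one-sided Fisher's exact test, p = 5.0e-05). The shared rises were miR-1246, miR-222-3p, miR-3663-3p, miR-3665, miR-3960, miR-4530, miR-4739 and miR-6090, and the shared falls miR-7-5p, miR-155-5p, miR-210 and miR-374b-5p. Across miRNAs, which are not independent replicates, the changes correlated with r = 0.54, and with r = 0.31 over the 437 miRNAs outside the GC-rich list. These comparisons share no array, but both take the spread of each miRNA from the same fit over all 12 arrays. A small spread eases a call in both, so the calls are not independent and the Fisher p-values can overstate the sharing.

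Whether the response to CK1a loss differed between the p53 wild-type and p53-null lines was tested as the difference between the changes, wild-type minus p53-null. Each genotype was a single line, so such a difference cannot be assigned to p53 alone. miR-34a-5p rose by 1.02 log2 more in wild-type cells (SE 0.13, 95% confidence interval 0.75 to 1.29, adjusted p = 2.0e-04). miR-7-5p fell further in wild-type cells (-0.57, adjusted p = 0.023). miR-4465 (-0.83, adjusted p = 0.0017) and miR-31-5p (-0.53, adjusted p = 0.043), a miRNA often raised in colorectal tumours, had lower changes in wild-type than in p53-null cells. Of 469 miRNAs 11 passed, 2 higher and 9 lower, and 46 had an unadjusted p under 0.05. The others were miR-494 (1.47, adjusted p = 0.037), miR-630 (-0.97), miR-5703 (-0.81), miR-4281 (-0.71), miR-4516 (-0.57), miR-6126 (-0.56) and miR-4530 (-0.55). The difference was 0.40 for miR-22-3p (adjusted p = 0.054), 0.38 for miR-34b-5p (0.095), 0.26 for miR-34a-3p (0.42), -0.42 for miR-15a-5p (0.095) and -0.57 for miR-1246 (0.059), none of which passed.

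Of the lists only the GC-rich one differed (median -0.23, adjusted p = 2.2e-10, and adjusted p = 0.85 with an estimated correlation). Its medians in wild-type and p53-null cells were 0.42 and 0.30 for replicate 1, 0.24 and 0.29 for replicate 2, and -0.32 and 0.21 for replicate 3. Its difference kept its sign and passed without all of replicate 3 (-0.13, adjusted p = 2.5e-04), and was -0.15 without the wild-type siCK1a array and -0.11 without the wild-type control array of replicate 3. In it 3 of 32 were lower (miR-4281, miR-4530 and miR-4516) and 0 higher. The counts were 9 lower and 1 higher when adjusted over the list alone, and 11 and 1 at an unadjusted p under 0.05. In the p53-induced list miR-34a-5p alone passed (3 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.45). The other 13 lists lay between 0.30 and 0.92, and fry called 0 lists. The count of 11 was the least stable. It was 51 without the wild-type siCK1a array of replicate 3, 60 on slide 1 alone, 23 without the wild-type siCK1a array of replicate 1, 0 without replicate 2 and 13 with slide as a block. It was 2 without the wild-type siCK1a array of replicate 2 or any 1 of the p53-null arrays except the control of replicate 2 (4), and 4 and 3 without the wild-type control of replicate 1 or 3. miR-34a-5p and miR-4465 passed without each of the 12 arrays in turn. miR-34a-5p did not pass without all of replicate 2 (1.02, adjusted p = 0.0659), without scaling (adjusted p = 0.31) or when scaled over all miRNAs (0.0669).

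The p53 genotypes were then compared under control siRNA, p53-null minus wild-type. With a single line per genotype, the differences under either siRNA are between lines and cannot be assigned to p53 alone. miR-30a-5p, which represses the autophagy gene BECN1 among others, was at 3951 ± 160 in wild-type and 138.8 ± 9.82, near the floor, in p53-null cells (-4.83, adjusted p = 2.8e-18). miR-30a-3p was not above background on any p53-null array (604 ± 39.8 in wild-type cells, at least 4.39-fold higher, adjusted p = 2.5e-13). miR-34a-5p was higher in p53-null cells, 2028 ± 79.3 against 737 ± 60.2 (1.46, adjusted p = 9.8e-10), as were miR-34b-5p (0.79, adjusted p = 5.2e-07) and miR-34a-3p (0.44, adjusted p = 5.5e-04). miR-200b-3p, of the family that represses the ZEB factors of epithelial-mesenchymal transition, was at 1487 ± 55.9 against 544.1 ± 26.8 (1.45, adjusted p = 9.8e-10).

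Under control siRNA 78 miRNAs passed, 59 higher and 19 lower in p53-null cells, and 22.6% had an unadjusted p under 0.05. The largest rises also held miR-135b-5p (1.28, detected on 1 of 3 wild-type arrays), miR-222-3p (1.25), miR-29a-3p (1.15), miR-193a-3p (1.13), let-7b-5p (1.09), miR-200a-3p (1.07), miR-29b-3p (1.04), miR-221-3p (1.03), miR-221-5p (1.02) and miR-429 (0.92). The lower miRNAs also held miR-30c-5p (-1.71), miR-30e-3p (adjusted p = 7.2e-08), miR-584-5p (at least 1.47-fold lower, not above background on the p53-null arrays), miR-301a-3p (-0.44), miR-374a-5p (-0.36), miR-3132 (-0.34), miR-22-3p (-0.33, adjusted p = 0.0030), miR-18a-5p and miR-18b-5p (-0.32 each) and miR-331-3p (-0.32). Of the other p53 targets, miR-107 was higher (0.64, adjusted p = 3.5e-05) and miR-192-5p lower (-0.31, adjusted p = 0.016), while miR-194-5p (-0.20, adjusted p = 0.15) and miR-215 (-0.13, adjusted p = 0.40) did not pass.

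Of the lists, 7 of 15 passed, none with an estimated correlation. The miR-30 family shifted down (median -0.23, adjusted p = 9.3e-07, and adjusted p = 0.112 with an estimated correlation). Of 11 members 6 were lower, miR-30c-2-3p (-0.24) and miR-30e-5p (-0.23) among them, and miR-30b-5p was higher (0.49, adjusted p = 0.0055). The miR-29 family, which represses collagens and DNA methyltransferases, shifted up (median 0.84, adjusted p = 7.7e-04, and adjusted p = 0.112 with an estimated correlation), with 4 of 6 higher. The miR-200/miR-205 list shifted up (median 0.58, adjusted p = 0.0075, and adjusted p = 0.26 with an estimated correlation). miR-200b-3p, miR-200a-3p and miR-429, from one cluster, were higher, while miR-200c-3p (-0.02) and miR-141-3p (-0.11), from another, did not pass. The let-7/miR-98 family, which represses RAS and HMGA2, shifted up (median 0.34, adjusted p = 0.010, and adjusted p = 0.43 with an estimated correlation), with 5 of 12 higher, led by let-7c (0.90), let-7b-5p (1.09), let-7i-5p (0.53) and let-7e-5p (0.47). Some probes within the let-7 family and within the miR-29 family are near-identical in sequence. Members of these families may share signal, which was not separated, so their counts need not be of independent changes. The miR-181/miR-221/miR-222 list (median 0.19, adjusted p = 0.0026, and adjusted p = 0.36 with an estimated correlation) had 4 of 9 higher, all from miR-221 and miR-222, miR-222-5p at 0.38. The inflammation-linked list (median 0.35, adjusted p = 0.0033, and adjusted p = 0.19 with an estimated correlation) had 5 of 8 higher, miR-155-5p (0.80), miR-125b-5p (0.68), miR-203a (0.55), miR-132-3p (0.37) and miR-21-5p (0.33), the last of which was at -0.032 with the authors' values (adjusted p = 0.97).

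When adjusted over the list alone, the higher and lower counts under control siRNA were 1 and 6 for miR-30, 4 and 0 for miR-29, 3 and 0 for miR-200/miR-205, 7 and 1 for let-7/miR-98, 4 and 0 for miR-181/miR-221/miR-222 and 6 and 0 for the inflammation-linked list. The GC-rich list shifted down slightly (median -0.05, adjusted p = 0.0026, and adjusted p = 0.66 with an estimated correlation). Of its 32 members limma called 0, over all miRNAs or over the list alone, and 5 had an unadjusted p under 0.05. Its median was 0.03 without the wild-type control array of replicate 3. In the p53-induced list 6 of 17 were higher and 3 lower, over all miRNAs and over the list alone, and the list did not pass (adjusted p = 0.97). The other 7 lists lay between 0.25 and 0.82, and fry called 11 lists. The count of 78 was 82 with slide as a block, 80 with a replicate block and 48 without replicate 2, and on slide 1 alone 190 were higher and 24 lower. Scaled by the median of detected miRNAs, 43 were higher and 34 lower, and with the authors' values 52 and 60. let-7/miR-98 lost its call without the wild-type control array of replicate 3 (adjusted p = 0.051). Of 31 control probes 11 were higher in p53-null cells and 0 lower, and the median log2 difference of all tested miRNAs was 0.081. A shift left by the scaling may add to the excess of higher calls and was not separated from it.

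With siCK1a the genotypes differed at 104 miRNAs, 79 higher and 25 lower in p53-null cells, with 30.1% at an unadjusted p under 0.05. miR-30a-5p was again lower (5315 ± 285 in wild-type and 137.7 ± 10.2 in p53-null cells; -5.27, adjusted p = 6.4e-19), as were miR-30a-3p (at least 5.24-fold), miR-30c-5p (-1.77) and miR-30e-3p (-1.02). miR-7-5p was 1.14 log2 higher in p53-null cells (1714 ± 45.1 against 779 ± 82.7, adjusted p = 6.4e-09) and miR-34a-5p 0.45 higher (adjusted p = 0.0012). miR-22-3p was lower (-0.73, adjusted p = 4.6e-07).

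The largest rises under siCK1a were those of miR-200b-3p (1.37), miR-222-3p (1.22), miR-135b-5p (1.11), miR-221-3p (1.10), miR-200a-3p (1.10), miR-193a-3p (1.09), miR-221-5p (1.01), miR-15a-5p (0.96), miR-125b-5p (0.93), miR-155-5p (0.93) and miR-151a-5p (0.93). Further lower miRNAs were miR-494 (-1.02), miR-1973 (-0.84), miR-584-5p (at least 1.40-fold lower), miR-5006-5p (-0.44), miR-374a-5p (-0.44), miR-194-5p (-0.41) and miR-149-5p (-0.41). Of the p53 targets, miR-107 (0.71) and miR-34b-5p (0.41) were higher and miR-192-5p lower (-0.29), while miR-34a-3p (0.18, adjusted p = 0.15) and miR-215 (-0.13) did not pass.

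Under siCK1a 5 of 15 lists passed. The miR-30 family was lower (median -0.30, adjusted p = 1.8e-06, and adjusted p = 0.14 with an estimated correlation), with 6 of 11 lower and miR-30b-5p higher (0.71). The miR-29 family (median 0.61, adjusted p = 0.0076, and adjusted p = 0.23 with an estimated correlation) had 5 of 6 higher, led by miR-29a-3p (0.87), miR-29b-3p (0.90), miR-29c-3p (0.78) and miR-29b-1-5p (0.45). The miR-181/miR-221/miR-222 list (median 0.20, adjusted p = 0.0097, and adjusted p = 0.46 with an estimated correlation) had 4 of 9 higher, and the miR-200/miR-205 list (median 0.54, adjusted p = 0.023, and adjusted p = 0.45 with an estimated correlation) 3 of 6. The let-7/miR-98 family (median 0.35, adjusted p = 0.024, and adjusted p = 0.50 with an estimated correlation) had 6 of 12 higher, let-7c (0.78), let-7b-5p (0.76), let-7a-5p (0.58) and let-7e-5p (0.39) first. Members of the let-7 and miR-29 families may share signal here too. When adjusted over the list alone, the higher and lower counts were 1 and 6 for miR-30, 5 and 0 for miR-29, 5 and 0 for miR-181/miR-221/miR-222, 4 and 0 for miR-200/miR-205 and 8 and 0 for let-7/miR-98. In the GC-rich list 12 of 32 were higher and 1 lower (14 and 1 over the list alone; adjusted p = 0.22). In the p53-induced list 6 were higher and 4 lower (7 and 4 over the list alone; adjusted p = 0.72), and the other 8 lists lay between 0.068 and 0.98.

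Fry called 10 lists under siCK1a, and of 31 control probes 10 were higher and 0 lower. The median log2 difference of all tested miRNAs was 0.085, and a shift left by the scaling was not separated from the excess of higher calls here either. The let-7/miR-98 and miR-200/miR-205 calls ended under quantile normalization (adjusted p = 0.13 and 0.072), and that of miR-29 too (0.064). The let-7/miR-98 call also ended without the wild-type siCK1a array of replicate 1 (0.176) or the p53-null siCK1a array of replicate 3 (0.0825). The count of 104 was 111 with slide as a block, 105 with a replicate block and 62 without replicate 2, and on slide 1 alone 92 were higher and 42 lower. Scaled by the median of detected miRNAs, 60 were higher and 49 lower.

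**Figure D3:**
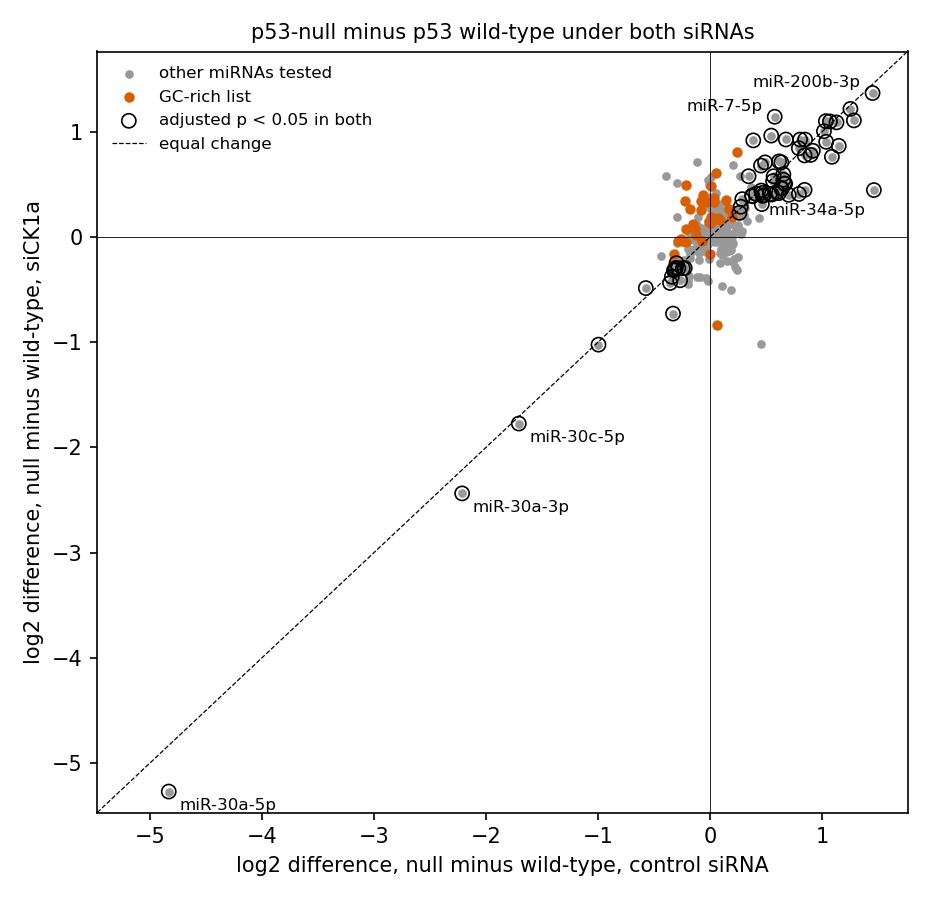
Log2 difference of p53-null minus wild-type cells with control siRNA (x axis) and with siCK1a (y axis) for the 469 tested miRNAs, each point a mean over 3 against 3 arrays; the GC-rich list is coloured and miRNAs that passed under both siRNAs are ringed. miR-30a-5p lies at -4.83 and -5.27, miR-200b-3p at 1.45 and 1.37, miR-34a-5p at 1.46 and 0.45, and miR-7-5p at 0.58 and 1.14.

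Under both siRNAs 68 miRNAs passed, 52 higher and 16 lower in p53-null cells, where independent lists would share 17.3 (one-sided Fisher's exact test, p = 5.2e-44). Across miRNAs the genotype differences correlated with r = 0.86, and with r = 0.89 outside the GC-rich list. These comparisons share no array, but they too share the estimate of the spread of each miRNA. Their calls are therefore not independent, and the Fisher p-value can overstate the sharing.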

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

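The tests of array background, of exchanged labels in replicate 3 and both tests on miR-34a-5p in p53-null cells were chosen after the results were seen; the others were written before. With 3 arrays per group no test for single outlying arrays was run. The responses to siCK1a of 11 miRNAs and 1 list differed between the genotypes by a test of the difference itself, given as wild-type minus p53-null; the list did not pass with an estimated correlation (adjusted p = 0.85), and fry did not call it (adjusted p = 0.80). They were miR-34a-5p (1.02), miR-494 (1.47), miR-630 (-0.97), miR-4465 (-0.83), miR-5703 (-0.81), miR-4281 (-0.71), miR-4516 (-0.57), miR-7-5p (-0.57), miR-6126 (-0.56), miR-4530 (-0.55), miR-31-5p (-0.53) and the GC-rich list (median -0.23). Of these miRNAs, miR-34a-5p (0.93 to 1.10) and miR-4465 (-0.90 to -0.73) passed without each of the 12 arrays in turn, miR-7-5p without each of 6 and miR-494 without each of 4, and the other 7 in 2 or 3 of the 12 omissions. The list's median was -0.13 without replicate 3, -0.15 without its wild-type siCK1a array and -0.11 without its wild-type control array; in wild-type and p53-null cells it was 0.42 and 0.30 for replicate 1, 0.24 and 0.29 for replicate 2 and -0.32 and 0.21 for replicate 3. The count of 11 was 51 and 23 without the wild-type siCK1a array of replicate 3 and 1, 2 without that of replicate 2, and 4 and 3 without the wild-type control array of replicate 1 and 3. It was 4 without the p53-null control array of replicate 2 and 2 without each of the other 5 p53-null arrays. Of 100 assignments of the siRNAs within each genotype, the real one included, 8 called at least 11 miRNAs, the highest other one 59. Such assignments take it that siCK1a had no effect in either line, not that its effects were equal. Those that exchange siRNAs within a line can also hold real responses. The 8 of 100 therefore cannot decide whether chance gave this count, and chance is not excluded.

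For the comparisons of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05. In p53-null cells siCK1a called 47 miRNAs in the real split and 0 in the highest other. For the genotypes these were 78 and 0 under control siRNA and 104 and 0 under siCK1a, and 1 of 10 splits, the real one, reached the real count in each of these 3. In wild-type cells 2 of 10 splits reached 17, the other with 84, which points to a structure of the samples: it exchanges the arrays of replicate 3, both on the slide that holds replicate 3 alone. With slide as a block the real count was 18.

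The GC-rich or structural-RNA-like list was higher after siCK1a in both genotypes, with a median of 0.24 in p53-null and 0.13 in wild-type cells (-0.02 there without the siCK1a array of replicate 1, and -0.32 in the pair of replicate 3, where the median of all miRNAs was -0.22), though neither passed with an estimated correlation (adjusted p = 0.68 and 0.51). A trend with GC content existed outside the list (r = 0.15, permutation p = 0.0021). After its removal the list's median in p53-null cells was 0.225 (bootstrap 95% interval over list members 0.128 to 0.415, and 0.149 with a loess curve). This lay above the third of its size, 0.0813, set as the bound, so the tables argue against this trend as the whole cause there. In wild-type cells the interval after removal held 0 (0.0937, -0.00737 to 0.222). The bootstrap held the fit fixed. The fit was also extended beyond most of its range, as the median GC content was 54.8% outside the list and 82.6% in it. Only 30 of 437 miRNAs outside reached the latter. In p53-null cells these 30 had a median change of 0.0737, and 6 of them were called higher. Over the 6 pairs of arrays with the same number, the list's change followed the ratio of negative-control signals (r = -0.94, exact p = 0.00278), yet the line gave 0.320 at equal background (0.302 to 0.385 without each pair in turn), and the 1 pair with backgrounds within 5% gave 0.304, which argues against background as the whole cause but leaves it a part in the size. Brighter control spots are argued against by 8 control probes with a median of -0.0992 in p53-null cells. A response of the cells and a change in RNA quality remain open, and neither was tested, as the series holds no measure of RNA integrity.

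miR-34a-5p was higher in p53-null than in wild-type cells under control siRNA (1.46), although p53 induces it. Signal from family members with a near-identical sequence may add to it. Of the 3 members tested, miR-449a was detected on 1 of 3 p53-null control arrays and miR-34c-5p and miR-449b-5p on 0, which is 1 of 9 pairs. miR-34a-5p was detected on all 3 of these arrays, which argues against miR-34c-5p and miR-449b-5p as its source. miR-34b-5p was left out of this test and was detected on all 12 arrays, so the explanation stays open for the family. The other arm of the hairpin, miR-34a-3p, was also higher in p53-null cells under control siRNA, and it was not part of this test either. An exchange of the labels of the 2 cell lines would put the larger response to siCK1a in the arrays labelled p53-null, and the difference of 1.02 in favour of those labelled wild-type speaks against it without forbidding it, because the genotypes were taken from the labels. A p53-independent difference between the 2 lines stays open and untested, with 1 line per genotype.

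In wild-type cells the pair of arrays of replicate 3 ran against the others: across miRNAs its changes correlated with those of pairs 1 and 2 at r = -0.07 and 0.22, against 0.82 between these, with a median change of -0.22 over all miRNAs. Exchanged labels of its 2 arrays would turn its changes round, but over the 47 miRNAs called in p53-null cells they correlated with the changes there at r = 0.546 (bootstrap 0.196 to 0.758; 0.683 and 0.676 for pairs 1 and 2; 0.393, 0.123 to 0.603, without miR-1246), which argues against an exchange; over the 13 in the GC-rich list r was 0.931, with 8 of 13 in the same direction. Over the 34 outside that list the correlation (r = 0.233, bootstrap -0.0928 to 0.524) and the test first written, their median signed change (0.118, -0.0183 to 0.148), were undecided. The higher background of its siCK1a array could account for part of the pattern, since over 437 miRNAs outside the GC-rich list the deviation of this pair rose with the mean level (Spearman rho 0.340, above the bound of 0.3). No biological explanation was tested, as nothing in the design sets replicate 3 apart except its slide.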

How the results depend on the processing

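The 5 settings of background, GC content and list members were chosen after the results were seen, and the others before. Counts of called miRNAs are given as a % of those tested, in the order siCK1a in wild-type cells, siCK1a in p53-null cells, their difference, and the genotypes under control siRNA and under siCK1a, where the values of the report are 3.62, 10.02, 2.35, 16.6 and 22.2. Over 40, 40, 39, 40 and 40 settings, the report's included, counts stayed within 1.5 times in 19, 19, 13, 33 and 36 others. Where they did not, the cause was not tested, unless fewer arrays or another threshold made the change. They were 5.97, 14.7, 0.640, 12.2 and 20.7 when scaled by the 75th percentile over all miRNAs, 9.17, 20.9, 1.28, 20.9 and 24.5 with quantile normalization, 7.25, 13.2, 2.35, 16.4 and 23.2 when scaled by the median, and 1.92, 6.40, 0, 7.46 and 10.2 without scaling. Higher and lower calls, 12 and 5, 30 and 17, 2 and 9, 59 and 19, and 79 and 25 in the report, were in wild-type cells 25 and 3 with the 75th percentile over all miRNAs, 30 and 4 with the median and 8 and 1 without scaling. In p53-null cells they were 47 and 15 with the median and 30 and 0 without scaling, and for the difference 0 and 3 with the 75th percentile over all miRNAs. For the genotypes under control siRNA they were 50 and 48 with quantile normalization and 43 and 34 with the median, and under siCK1a 53 and 44 with the 75th percentile over all miRNAs, 67 and 48 with quantile normalization, 60 and 49 with the median and 24 and 24 without scaling. With the authors' values they were 24 and 28, 66 and 53, 9 and 20, 52 and 60, and 81 and 61, with the brightest probe 32 and 41 in p53-null cells, 56 and 30 and 67 and 52 for the genotypes, and with quantile normalization 27 and 16 in wild-type cells. The larger of the 2 directions also turned round in p53-null cells with array weights (114 and 152) and without the GC-rich list's miRNAs (16 and 17), and for the genotypes under control siRNA when adjusted for GC content (49 and 67). For the difference it did so with a doubled floor (5 and 4), no filter (1 and 0), array weights (26 and 15), a log2 change of at least 1 (2 and 0) and the negative controls subtracted (3 and 2), on slide 1 alone (39 and 21) and without the wild-type siCK1a array of replicate 3 (30 and 21). The median of all miRNAs shifted by over 0.1 without scaling (-0.12 for both genotype comparisons) and, in wild-type cells, with no background correction or the negative controls subtracted (0.12 each). The % called was 0.548, 1.35, 0.0499, 3.34 and 3.59 with no filter, where 2006 were tested, 15.6 in p53-null cells with the brightest probe, and 11.1, 25.4, 6.18, 23.9 and 30.3 with the authors' values. It was 21.2, 15.05, 11.9, 42.4 and 26.5 on slide 1 alone, 2.04 and 22.9 for siCK1a with only the arrays of the groups compared, which gives no value for the difference, 5.33, 56.7, 8.74, 65.5 and 18.8 with array weights, whose estimation did not converge fully, 0.426, 1.07, 0.426, 2.99 and 2.77 at a log2 change of at least 1, and 4.48 for the difference at an adjusted p under 0.1. With no background correction it was 6.18 in wild-type cells, with an offset of 0 it was 8.32 and 18.6 for siCK1a, and with the negative controls subtracted 6.40, 17.7 and 1.07 for the first 3. It was 7.04, 20.04 and 8.32 for the first 3 when adjusted for GC content, and 2.52 in wild-type cells and 1.60 for the difference without the GC-rich list's miRNAs. Leaving out a replicate or 1 array gave 0.636 to 21.2, 2.75 to 15.95, 0 to 11.9, 10.2 to 42.4 and 13.1 to 28.1. Single arrays that moved a count by over 1.5 times were, in wild-type cells, the siCK1a arrays of replicate 1 (5.50) and 3 (14.3) and the control array of replicate 1 (2.33). In p53-null cells they were the p53-null control arrays of replicates 1 (6.14), 2 (5.53) and 3 (6.32), the siCK1a arrays of replicates 1 (6.17) and 2 (5.76) and the wild-type siCK1a array of replicate 3 (15.95). For the difference they were each array except the wild-type control of replicate 2: 0.848 and 0.625 without the wild-type controls of replicates 1 and 3, 4.86, 0.426 and 10.4 without the wild-type siCK1a arrays of replicates 1, 2 and 3, 0.851 without the p53-null control of replicate 2 and 0.420 to 0.426 without the other 5. Lists called, 4, 2, 1, 7 and 5 in the report, were 2 and 1 for siCK1a with the 75th percentile over all miRNAs, 3 for the genotypes under siCK1a with quantile normalization or the median, 1 in p53-null cells with the median or without scaling, and 8, 4, 2, 8 and 9 with no filter. They were 0 in each comparison with an estimated correlation, 0, 1, 0, 11 and 10 with fry, 2 and 1 for siCK1a when adjusted for GC content, and 0 in p53-null cells and for the difference without the GC-rich list's miRNAs. Leaving out a replicate or 1 array gave 2 to 6, 1 to 2, 1 to 2, 5 to 7 and 4 to 6 lists. With replicate as a block 18, 44, 11, 80 and 105 miRNAs were called, and the only named miRNA that lost its call was miR-6126 in the difference (adjusted p = 0.0711), where miR-1246 newly passed (-0.57, adjusted p = 0.014). The numbers did not pair the arrays in wild-type cells or for the difference (lowest correlation -0.42). For the calls of named miRNAs, 4610 of 5215 values under alternatives kept direction and side of the threshold, 604 no longer passed and 1 turned round, miR-21-5p for the genotypes under control siRNA with the authors' values (-0.032, adjusted p = 0.97, against 0.33). For 19 calls of lists 77 of 604 values no longer passed. By the direction of camera none turned round, but the median of the GC-rich list changed sign in wild-type cells without replicate 1 or its siCK1a array (-0.02 each, against 0.13) and for the genotypes under control siRNA with no filter (0.0015) or without the wild-type control array of replicate 3 (0.03, against -0.05). In all, 190 values of named miRNAs without a call newly passed. The planned normexp correction from spot means and local background was not run, as the files lack the columns it needs. The 75th percentile of detected miRNAs lay 5.15 to 7.79 times over the negative controls. The self-test, whose noise can be too small, recovered 34.7% of changes of 0.4 log2. What limited this recovery was not tested.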

Other observations

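Among the values below, the miRNAs of the first paragraph were chosen after their values were seen, and the cluster test was written before. Some of these miRNAs belong to lists that did not pass for the genotypes. They are miR-151a-5p (Wnt/MYC-linked) and miR-23a-3p, miR-27a-3p and miR-24-3p (miR-23/27/24). miR-151a-5p, from an intron of the focal adhesion kinase gene PTK2, was at 1037 ± 34.1 in p53-null and 575.9 ± 19.1 in wild-type cells under control siRNA (0.85, adjusted p = 2.8e-07) and 0.93 higher under siCK1a (adjusted p = 9.9e-08). It passed under each of 6 settings, the 5 scalings and the authors' values. The 5 members miR-320a to miR-320e, whose sequences are near-identical so that their probes may share signal, were higher by 0.46 to 0.67 under control siRNA (0.33 to 0.73 over these 6 settings), where each passed except miR-320c without scaling. Under siCK1a they were higher by 0.42 to 0.51 (0.27 to 0.51 over the 6), and none of the 5 passed without scaling (adjusted p = 0.060 to 0.17). miR-100-5p, which targets MTOR, was higher by 0.79 (adjusted p = 1.0e-05) and 0.84 (adjusted p = 5.1e-06), passing in 5 and 6 of the 6 settings. Its range over these settings was 0.52 to 0.79 under control siRNA and 0.48 to 0.84 under siCK1a. miR-23a-3p (0.65, adjusted p = 1.2e-04) and miR-27a-3p (0.64, adjusted p = 3.9e-05), from one cluster, were higher under control siRNA. Over the 6 settings they were at 0.39 to 0.65 and 0.29 to 0.64, passing in 4 and 5. Under siCK1a they were at 0.60 (0.32 to 0.60 over the 6 settings) and 0.46 (0.09 to 0.46), passing in 3 and 1 of the 6. Their neighbour miR-24-3p, also made from another cluster, was at 0.23 (adjusted p = 0.063), and below 0 under quantile normalization (-0.07) and with the authors' values (-0.01). Under siCK1a it was at 0.07 (adjusted p = 0.59), and lower under quantile normalization (-0.23, adjusted p = 0.013) and with the authors' values (-0.23, adjusted p = 0.030), the opposite direction to miR-23a-3p and miR-27a-3p.

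As a hypothesis, miRNAs from hairpins within 10000 bp of each other may change together because they share a transcript. The 352 hairpins matched by tested miRNAs held 28 clusters of at least 2, with 68 hairpins. For the genotypes under control siRNA the mean absolute difference of log2 change within clusters was 0.129, against a median of 0.235 when the hairpins were permuted (permutation p = 0.0048). For siCK1a in wild-type cells it was 0.0756 against 0.153 (permutation p = 1e-04, the smallest that these permutations can give). In the other comparisons, which had no test written before, the permutation p was 1e-04 for the genotypes under siCK1a (0.0943 against 0.270), 0.0057 for siCK1a in p53-null cells and 2e-04 for the difference. The permutations drew on all 352 hairpins, of which only 68 lay in clusters. Hairpins in clusters that merely change less than the others would also give a smaller difference. The test therefore cannot show that neighbours move together. Neighbours with near-identical sequences may also share signal on the array, which was not separated from shared transcription.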
